A study of Mus musculus with 6 samples.

How the data were processed

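Gene expression was measured by sequencing mRNA libraries from 6 organoid cultures, 3 lines with 2 hairpins each. Per the labels' protocols, organoids were grown in Matrigel, RNA was extracted with Trizol and an RNeasy kit, and Illumina mRNA libraries were made. The treatment label says that the hairpins were delivered by virus, whereas the series' design text speaks of transfected plasmids. The authors deposited estimated counts per Ensembl gene, 1 table per library with 54453 genes, and per the submitters' processing notes the tools were Salmon 1.4.0 and DESeq 2 and the build was GRCm38 (mm10). The role of the second tool, the transcript annotation, the strand setting, trimming and the way transcripts were summed to genes are not given in the sources used here. The deposited estimated counts were not scaled for depth, since their totals ran from 24035559 to 36235773 per library. Salmon shares reads among transcripts of similar sequence by expectation, so genes with near-identical copies can trade counts between libraries. Since no strand setting is stated, it is not known whether reads of overlapping antisense genes were told apart.

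The estimated counts were rounded to whole numbers and analysed in R 4.3.3. Gene symbols, positions and biotypes came from a GENCODE annotation of GRCm38, the build named in the processing notes, and 54131 of the 54453 identifiers matched a symbol while 322 did not. Genes with low counts were removed with edgeR's filterByExpr on the hairpin groups (minimum count 10), which left 14169 genes holding at least 99.8% of the counts of each library. Library sizes were scaled by TMM, and CPM values refer to the scaled library size unless called unnormalised. The log2 CPM used for principal components had a prior count of 2. No gene took more than 0.904% of all counts. The top 5 were mt-Co1 with that share, Eef1a1 (0.817%), Pkm (0.434%), Gapdh (0.425%) and Eef2 (0.393%).

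The knockdown was tested with edgeR 4.0.16 (quasi-likelihood F-test, robust dispersions) with terms for line and hairpin, over all 6 libraries, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The line was a term because each line received both hairpins. The design gives 2 residual degrees of freedom, the fit added 4.43 prior ones, and the common biological coefficient of variation was 15.5%. The pairing was checked on the data, where the deviations of the 2 libraries of a line from their group means correlated across genes at 0.621 in T91, 0.666 in T113 and 0.662 in T118, and between -0.417 and -0.221 for libraries of different lines. Centring on group means makes the latter negative on average once the former are positive, so their sign adds nothing to the check. Differences between lines were tested with the F-test of both line terms in the same fit and with pairwise contrasts. The libraries of a line carry different hairpins, so the spread behind that test is what an average knockdown effect leaves over. No pair of libraries held identical values, and chi-square statistics per degree of freedom between libraries ran from 24.9 to 105, far above sampling noise.

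Gene lists, 31 for pathways and complexes and 7 for other cell types and RNA quality, were fixed together with the tests, the rule for named genes and most alternatives before the data were examined. Lists with at least 3 members past the filter were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 33 lists tested. All 715 list genes were found in the tables.

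The text names Scrib and, in each direction, genes past the adjusted threshold with the same direction in all 3 lines, an average log2 CPM of at least 2 and no clone or pseudogene symbol, by size of the fold change. Where too few passed, each direction was filled up to 8 genes by smallest unadjusted p, and these are said not to have passed. It also names up to 4 members per list by p, up to 5 genes per line that were higher in it than in both other lines, 5 sex-linked genes and the top 5 genes by counts. Some genes and lists that these rules take in are not reported here. Genes named outside this rule were chosen after their values were seen. These are Hnf4a, Foxa2, Gata4 and Gata6 of the classical list, Col3a1, Lyz2 and C1qa among other-cell markers, and the genes of the closing observations.

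Alternative settings chosen in advance were a fit without the line term, DESeq2 size factors, no low-count filter, a stricter filter (average CPM of at least 5), DESeq2 1.42.0 with and without the line term, limma-voom, non-robust dispersions, the legacy quasi-likelihood method, a minimum absolute log2 fold change of 1, a threshold of 0.1 and leaving out each line or library. For lists they were an estimated correlation and fry. For the lines they also included a fit without the hairpin term. The count of lists with the tested direction in each line, size factors of DESeq2 for the lists, and a test without clone-named genes were added after the data were seen. The knockdown tests of edgeR, DESeq2 and limma-voom and the camera test were first run on simulated counts for the 14169 genes, with 200 changed genes in each of 3 runs. In this simulation of the knockdown comparison edgeR called 0.498% of genes changed 1.5-fold, 40.8% of those changed 2-fold and 91.4% of those changed 4-fold, and 3.97% of its calls were false. DESeq2 called 35.8%, 84.1% and 100% of these genes, and 30% of its calls were false (192 of 640 over the 3 runs). Such a share depends on how many genes were changed in the simulation. DESeq2 was also run on all 54453 genes of the data, not on the 14169 of the simulation. The 30% is therefore not an estimate for its calls in the data. A simulated list lowered by 0.5 on the log2 scale was called in 3 of 3 runs by camera with the preset correlation and in 0 of 3 with an estimated one. The simulated genes were drawn independently of one another, whereas the estimated correlation in the data was 0.542 for the classical list, the one lowered in simulation. These runs therefore do not show how either setting behaves with correlated genes.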

Results

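RNA was sequenced from 3 mouse pancreatic tumour organoid lines of the KPC kind, named T91, T113 and T118, each carrying a short hairpin RNA against Scrib or a control hairpin against Renilla luciferase. KPC is the usual name for a family of mouse models of pancreatic ductal adenocarcinoma (PDAC). The labels give the genotype as KPF/FC, which is not spelled out in the sources used here. Organoids are epithelial cultures kept in a gel of extracellular matrix, here Matrigel. Each line gave 1 library with the Renilla hairpin and 1 with the Scrib hairpin, so that each group held 3 libraries and each library had its counterpart in the same line. The T91 line came from a female mouse and was at passage 10, and the T118 and T113 lines came from males and were at passages 11 and 13. Summed estimated counts per library were 29910162 and 24035559 for T91 (Renilla, then Scrib hairpin), 29985089 and 27990393 for T118, and 36235773 and 29817060 for T113. At these depths 1 count was worth between 0.0269 and 0.0421 CPM (counts scaled to library size). The 3 libraries of a group came from separate tumour lines, but each line was sampled once per hairpin, so the spread within a line was not measured.

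The first comparison checked the target itself. Scrib, which encodes a scaffold protein of the basolateral polarity complex of epithelial cells, fell to 19.3% of its control level. It stood at 164 ± 11.1 CPM with the Renilla hairpin and at 31.6 ± 2.95 CPM with the Scrib hairpin (SD, n = 3 each). The log2 ratio within a line was -2.57 in T91, -2.16 in T113 and -2.39 in T118. The log2 fold change was -2.38 with a standard error of 0.12 (95% interval -2.65 to -2.10), a 5.19-fold difference, with an adjusted p of 0.00582 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scrib (ENSMUSG00000022568) is a protein-coding gene on the minus strand of chromosome 15, from 76047158 to 76069784 in GRCm38. The sequence of hairpin number 5523 and the exon it matches are not given in the sources used here.

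The first principal component of log2 CPM held 44.5% of the variance and the second 30.1%. The first separated the 3 lines, and the second set T113 apart from T91 and T118. Over all genes tested, the line accounted for 73.9% of the variance (2 degrees of freedom), the hairpin for 10.2% (1) and the remainder for 15.8% (2). The remainder is the part of the knockdown response that differed between lines plus noise. The share of the hairpin holds such noise as well, so it is not the size of the knockdown effect alone.

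**Figure D1:**
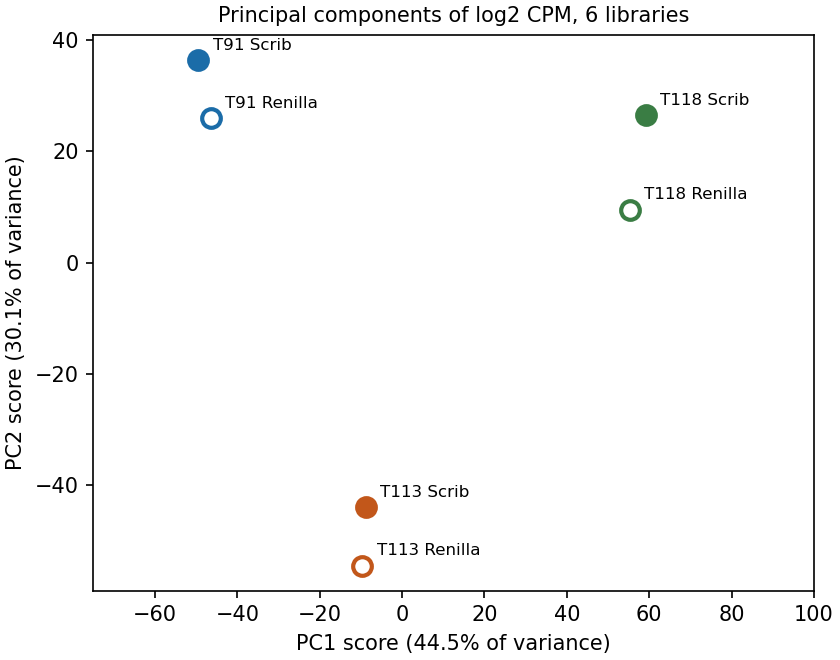
Scores of the 6 libraries on the first (x axis, 44.5% of variance) and second (y axis, 30.1%) principal components of log2 CPM. Open circles are libraries with the Renilla hairpin and filled circles those with the Scrib hairpin, coloured by organoid line, and the 2 libraries of each line lie next to each other.

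The second comparison asked which genes change when Scrib is depleted in tumour organoids. Apart from Scrib, the named genes with the smallest p-values were lower after knockdown in each line, although none of them passed edgeR's test, and Muc4, Dmbt1 and Agr2 had the largest fold changes among them. Muc4, a membrane-bound mucin, was at 22.1 ± 13.6 CPM in control and 9.89 ± 6.21 CPM in knockdown libraries (SD, n = 3 each), a log2 fold change of -1.16 with a standard error of 0.14. Dmbt1, a mucosal scavenger-receptor glycoprotein, stood at 606 ± 375 and 221 ± 65.9 CPM (log2 fold change -1.33, standard error 0.18). Agr2, a protein disulphide isomerase needed for mucin folding, stood at 243 ± 245 and 126 ± 147 CPM (log2 fold change -1.12, standard error 0.16). The wide standard deviations come with the large differences between lines, since within each line the knockdown library was the lower one for all 3 of these genes. That shared direction was a condition for being named, so it is no separate support for a change.

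Of 14169 genes tested, 1 had an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and that gene was Scrib. No gene passed as higher after knockdown. At an unadjusted p under 0.05 there were 936 genes, 219 higher and 717 lower, where 708 would be called with no effect at all. Of the 3 other splits of the libraries that part all pairs, 1 gave more such genes (1455, with 725 one way and 730 the other) and 2 gave fewer (321, with 250 and 71, and 95, with 44 and 51). Of the other genes, the lowest adjusted p was 0.149, shared by Gm13040, Gm2436 and Gm2446, whose transcripts occur almost whole in other genes. DESeq2's Wald test with the same line term called 60 genes, 6 higher and 54 lower, and limma-voom called 8, 3 higher and 5 lower. Without the low-count filter the edgeR test called 64 genes, 10 higher and 54 lower. Each of these 3 counts holds 7 genes with 0 counts in all libraries of one group and at least 10 in each library of the other. Of these, 3 were higher and 4 lower, most are near-copies of other genes, and the 8 of limma-voom are these 7 and Scrib. The count without the filter holds further genes with log2 fold changes about as large, such as -8.48 and 8.24. Leaving out a line also moved the count, to 94 genes without T91, 9 without T113 and 25 without T118. Besides Scrib, the calls without T113 all had absolute log2 fold changes of at least 9.06. Of the 7 genes at 0 in one group, 4 were called without T113, and all 7 without T91 and without T118.

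The rule for named genes picked 7 further genes lower in all 3 lines, none past the edgeR test (adjusted p from 0.327 to 0.394 with Benjamini-Hochberg adjustment) and each called by DESeq2. Besides Muc4, Dmbt1 and Agr2 these were Papss2, an enzyme that makes the sulphate donor for glycan sulphation (log2 fold change -0.92, standard error 0.12), and Ceacam1, a cell adhesion glycoprotein (-0.83, standard error 0.11). Pigr, the receptor that carries polymeric immunoglobulin across epithelium, had a log2 fold change of -1.12 with a standard error of 0.16. Kdm7a, a histone demethylase, had one of -0.72 with a standard error of 0.10. Ceacam1 was the most abundant of these 4, at 416 ± 135 CPM in control and 232 ± 65.8 CPM in knockdown libraries (SD, n = 3 each). The 8 genes picked as higher in all 3 lines did not pass either (adjusted p from 0.422 to 0.692 by the same edgeR test). Among them, Pcyox1l had a log2 fold change of 0.66 (standard error 0.11), Atoh8, a basic helix-loop-helix transcription factor, of 0.96 (0.19), Scnn1a, a subunit of the epithelial sodium channel, of 0.57 (0.13) and Wnt4, a secreted signalling protein, of 0.51 (0.14). The RNA-binding protein gene Igf2bp1 had a log2 fold change of 0.57 (0.15), the long noncoding RNA Lncenc1 of 0.63 (0.17), Arhgap8 of 0.63 (0.17) and Ankrd1, a well-known YAP target, of 0.38 (0.11). Of these 8, Pcyox1l was called by DESeq2.

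**Figure D2:**
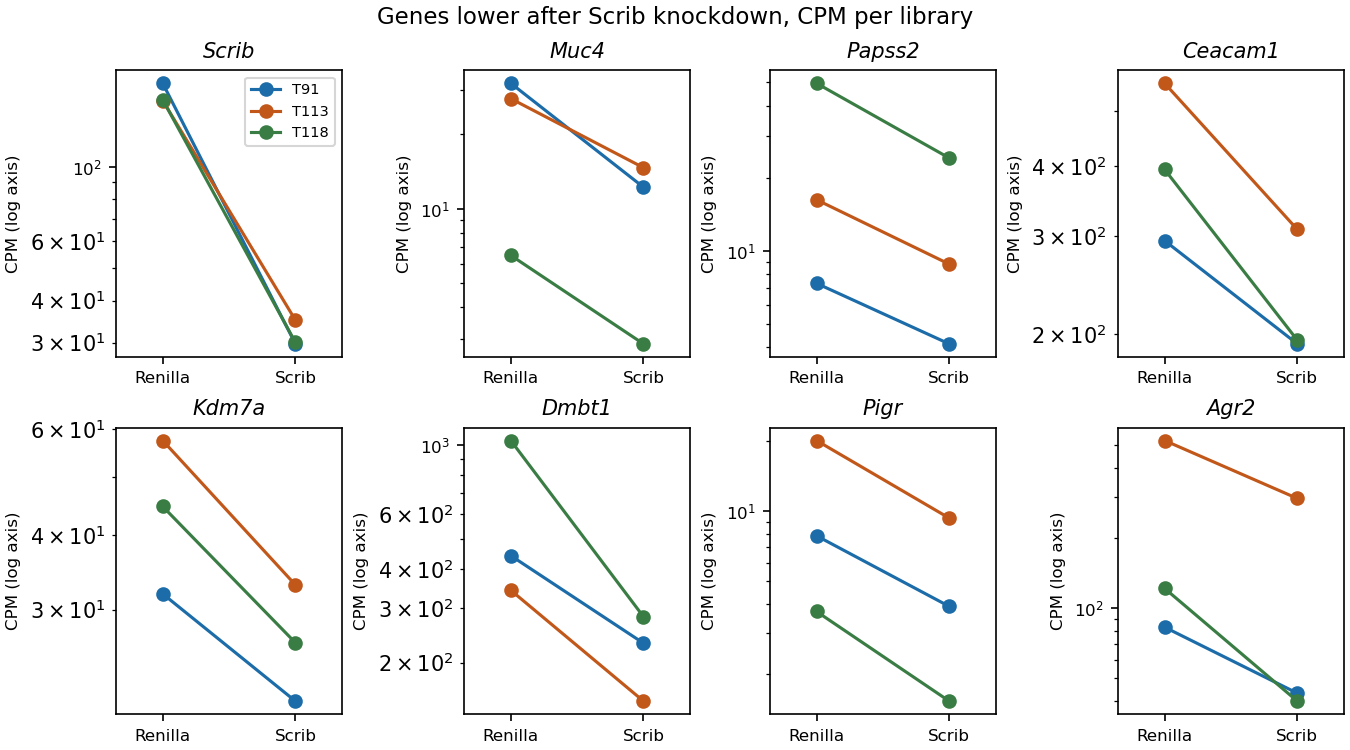
Normalised counts in CPM (log axis) of Scrib and of the 7 further genes picked as lower, with 1 line per organoid line joining its Renilla and its Scrib library. Scrib, the gene that passed edgeR's test, averaged 164 CPM with the Renilla hairpin and 31.6 CPM with the Scrib hairpin, with no overlap between the groups.

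Genes typical of the classical, gland-like subtype of pancreatic cancer were lower as a group after knockdown. Of 22 members of this list that passed the low-count filter (called measured from here on), 19 were lower and 3 higher, with a median log2 fold change of -0.48 over the lines and of -0.17 in T91, -0.39 in T113 and -1.05 in T118. Besides Agr2, the members with the smallest p-values were Muc13, a membrane mucin, at -1.16 with a standard error of 0.23, Tff2, a trefoil peptide secreted with mucus, at -0.84 with one of 0.20, and Myo1a, a brush border myosin, at -1.13 with one of 0.33. Among transcription factors of the list, the log2 fold change was -0.30 for Hnf4a (standard error 0.12), 0.06 for Foxa2 (0.09) and -0.07 for Gata4 (0.11). Gata6 had one of 0.75 (0.92), with a ratio of 0.01 in T91, 2.99 in T113 and -1.33 in T118. It was close to absent in the control libraries of T113 (0.0269 CPM) and T118 (0.102 CPM). No member passed over all genes tested, 10 lower members had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone, namely Agr2, Muc13 and Tff2. The list had an adjusted p of 3.45e-10 by limma's camera with a preset correlation, and an adjusted p = 0.625 with an estimated correlation. General epithelial genes had a median log2 fold change of -0.17 in the same fit (9 genes, from -0.25 to 0.06).

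**Figure D3:**
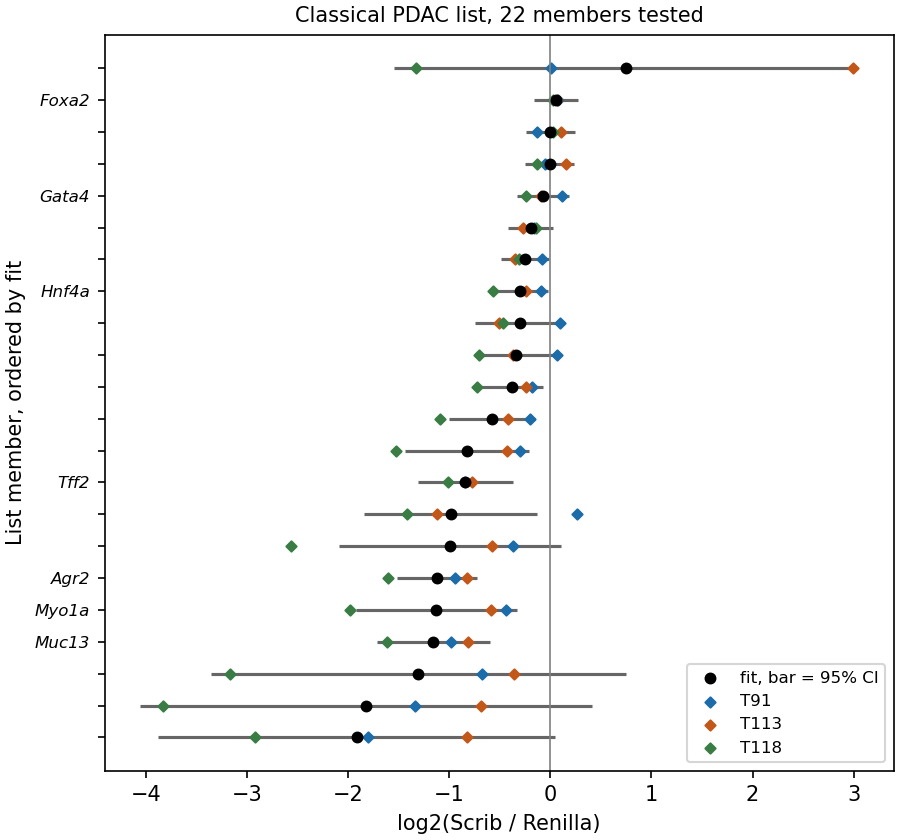
Log2 ratio of Scrib over Renilla hairpin (x axis) for the 22 measured members of the classical list. Members named in the text other than Gata6 are labelled, black points are the fit over the lines with 95% intervals, diamonds are the ratios in T91, T113 and T118, and 19 of the 22 fitted values lie below 0.

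Cell cycle genes were slightly higher, with 29 of 30 measured members above 0 and a median log2 fold change of 0.19. Their median ratio was 0.01 in T91, 0.26 in T113 and 0.30 in T118. Aurka, a mitotic kinase, was at 117 ± 9.81 CPM in control and 141 ± 7.86 CPM in knockdown libraries (SD, n = 3 each; log2 fold change 0.27, standard error 0.09). Cdc20, an activator of the anaphase-promoting complex, had a log2 fold change of 0.25 (0.09). No member passed over all genes tested or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The camera test gave an adjusted p of 3.45e-10, and an adjusted p = 0.625 with an estimated correlation. All 30 ribosomal protein genes measured were also above 0, by a median of 0.12, but their median ratio was 0.30 in T91, 0.09 in T113 and -0.02 in T118, and no member passed over all genes or adjusted over the list alone. That list had an adjusted p of 4.21e-06 by camera, an adjusted p = 0.735 with an estimated correlation and an adjusted p of 0.239 without T91.

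Genes of cell-to-cell and cell-to-matrix attachment were lower as groups. For integrins and basement membrane components 18 of 21 members were lower, with a median of -0.20 and per-line medians of -0.28 in T91, -0.21 in T113 and -0.26 in T118. Nid1, a basement membrane linker, had a log2 fold change of -0.45 (standard error 0.09), the laminin chain gene Lama3 of -1.82 (0.44) at 1.79 CPM in control, Itga2 of -0.39 (0.10) and the perlecan gene Hspg2 of -0.33 (0.09). In this list 6 lower members had an unadjusted p under 0.05, 1 (Nid1) passed adjusted over the list alone and 0 passed over all genes. Its adjusted p was 2.77e-06 by camera, and an adjusted p = 0.625 with an estimated correlation. For adherens junctions and desmosomes 19 of 22 members were lower, with a median of -0.15. The desmosomal cadherin gene Dsc2 had a log2 fold change of -0.44 (0.12), Dsg2 of -0.23 (0.10) and the E-cadherin gene Cdh1 of -0.19 (0.09), and none passed over all genes or adjusted over the list alone. For tight junctions 16 of 19 members were lower, with a median of -0.13, and 1 (Cldn6) passed adjusted over the list alone. Cldn6 had a log2 fold change of -0.59 (0.12), Cldn15 of -1.37 (0.42) and the adhesion receptor gene Cxadr of -0.31 (0.10). The camera adjusted p was 0.00796 for adherens junctions and desmosomes and 0.00251 for tight junctions, and an adjusted p = 0.625 with an estimated correlation for both. The adherens junction list missed the threshold in the fit without the line term (adjusted p of 0.0569), and the tight junction list missed it without T118 (adjusted p of 0.0545).

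No partner of Scrib in its polarity complex passed the test. The Scribble complex list had 6 measured members, and Scrib itself was the only one past the test over all genes or adjusted over the list alone. Of the partners, Dlg3 had a log2 fold change of -0.22 (standard error 0.10), Dlg1 of -0.10 (0.13) and Llgl1 of -0.04 (0.09). The list, which holds the target itself, had an adjusted p of 0.0135 by camera, an adjusted p = 0.625 with an estimated correlation and an adjusted p of 0.172 without T91. Of 14 measured members of the Par and Crumbs complexes 9 were lower. Pard3b had a log2 fold change of -0.55 (0.11) and was the 1 member that passed adjusted over the list alone, and Pard3 had one of -0.25 (0.09). That list did not pass (adjusted p of 0.2003 by camera).

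All 17 hypoxia genes measured were lower, with a median of -0.49, but the per-line medians were 0.10 in T91, -0.50 in T113 and -1.01 in T118. Vegfa, the angiogenic growth factor, had a log2 fold change of -0.49 (standard error 0.18), and Car9, a carbonic anhydrase induced by low oxygen, of -0.79 (0.33). No hypoxia gene passed over all genes or adjusted over the list alone. The adjusted p was 1.80e-05 by camera, and an adjusted p = 0.625 with an estimated correlation. For NF-kB and cytokine genes 16 of 19 members were lower, with a median of -0.29. The inflammatory regulator gene Nfkbiz had a log2 fold change of -0.39 (0.10), the cytokine gene Lif of -0.59 (0.16) and Il1a of -1.07 (0.34), and none passed adjusted over the list alone. The adjusted p was 0.000710 by camera, and an adjusted p = 0.625 with an estimated correlation. Of 16 immediate early and AP-1 genes 12 were lower, with a median of -0.32, and 2 passed adjusted over the list alone, Fosl2 at -0.64 (0.11) and Klf4 at -0.59 (0.15). Their adjusted p was 0.00251 by camera, an adjusted p = 0.718 with an estimated correlation and an adjusted p of 0.241 without T118.

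Of 18 ERK feedback and target genes 13 were lower, with a median of -0.16. The phosphatase gene Dusp4 had a log2 fold change of -0.35 (standard error 0.09), and the feedback inhibitor gene Spry4 of -0.28 (0.11). The list had an adjusted p of 0.0324 by camera and an adjusted p = 0.625 with an estimated correlation, and it missed the threshold without T91 (adjusted p of 0.0928) and without T113 (adjusted p of 0.192). Glycolysis genes were lower for 17 of 18 members (17 symbols, 1 of which has 2 gene identifiers), with a median of -0.18, a camera adjusted p of 0.00862 and an adjusted p = 0.748 with an estimated correlation. Without T118 their direction turned and the adjusted p was 0.733. Ductal identity genes were lower for 10 of 16 members, with a median of -0.21. Onecut2, a transcription factor of ductal and hepatobiliary cells, had a log2 fold change of -0.81 (0.14) and was the 1 member that passed adjusted over the list alone. The ductal list had an adjusted p of 0.0135 by camera, an adjusted p = 0.707 with an estimated correlation and an adjusted p of 0.305 without T118. Genes of the unfolded protein response were lower for 17 of 19 members, with a median of -0.16, an adjusted p of 0.0135 by camera and an adjusted p = 0.781 with an estimated correlation. That list missed the threshold without T113 (adjusted p of 0.192) and without T118 (adjusted p of 0.984). NRF2 targets were lower for 14 of 18 members, with a median of -0.05. The cystine transporter gene Slc7a11, at -0.48 (0.10), was the 1 NRF2 target that passed adjusted over the list alone. The NRF2 list had an adjusted p of 0.0287 by camera and an adjusted p = 0.649 with an estimated correlation. It missed the threshold without the line term (adjusted p of 0.0907), without T113 (0.0977) and without T118 (0.557).

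Most markers of other cell types were scarce, but the neural and Schwann marker Mbp was at between 71.3 and 107 unnormalised CPM in all 6 libraries. The fibroblast list had 3 measured members, all higher, with a camera adjusted p of 0.000710 and an adjusted p = 0.625 with an estimated correlation, and all 3 passed adjusted over the list alone but not over all genes. The type I collagen genes Col1a1 and Col1a2 had log2 fold changes of 1.60 (standard error 0.48) and 1.19 (0.46), but Col1a1 averaged 0.477 ± 0.0304 CPM in control and 1.78 ± 1.52 CPM in knockdown libraries (SD, n = 3 each), and both are also members of the mesenchymal list. Pdpn, the other member, was measured at between 12.4 and 102 unnormalised CPM in all 6 libraries and had a log2 fold change of 0.41 (0.12). In the T91 knockdown library, unnormalised CPM were 3.49 for Col1a1, 1.997 for Col3a1, 1.12 for the macrophage gene Lyz2 and 0.749 for C1qa, each higher there than in the other 5 libraries. Markers of endothelial cells (0 of 8 past the low-count filter), immune cells (1 of 17), acinar cells (2 of 14), islet cells (2 of 12) and MHC class II (1 of 7) had too few members to test.

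The camera test thus called 16 of 33 lists, 3 higher and 13 lower, and with an estimated correlation it called 0. That loss cannot be put down to correlation alone. The estimate was -0.0066 for integrins and basement membrane and 0.0101 for adherens junctions and desmosomes, near or below the preset 0.01, yet both calls were lost. For ribosomal proteins it was 0.970. In this design with 2 residual degrees of freedom, camera with an estimated correlation called 0 lists in every split of the libraries. It also called the lowered list in 0 of 3 simulated runs. A list that it did not call is therefore neither shown to be unchanged nor put down to chance by it. The directional fry test, which asks whether the members of a list move on balance one way, called 0 lists, and the mixed fry test called 2, integrins with basement membrane and the Scribble complex (adjusted p of 0.0490 for each). The Scribble complex list holds the target Scrib, so its calls do not show a response of the partners. The tested direction was seen in each of the 3 lines for 9 of the 16 lists, a count added after the data were seen. The 17 lists that did not pass camera had adjusted p from 0.104 to 0.960. YAP and TAZ target genes were among them (adjusted p of 0.625 by camera), with 9 of 20 members higher and 11 lower. Ankrd1 and Birc5 (0.26, standard error 0.09) lay above control, and F3 (-0.66, 0.21) and Nt5e (-1.27, 0.36) below it. Their median was -0.02 while camera put the list upward. The camera adjusted p was 0.557 for Hippo pathway components, 0.960 for mesenchymal transition, 0.957 for TGF-beta targets, 0.759 for Wnt targets and 0.830 for Notch targets. It was 0.936 for p53 targets, 0.136 for apoptosis regulators, 0.2003 for interferon response genes and 0.125 for basal-like and squamous PDAC genes. For metabolism it was 0.202 for cholesterol synthesis, 0.466 for fatty acid synthesis and 0.104 for oxidative phosphorylation. It was 0.656 for neural markers and 0.522 for mitochondrially encoded genes, which took between 1.69% and 2.32% of the counts of a library.

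**Figure D4:**
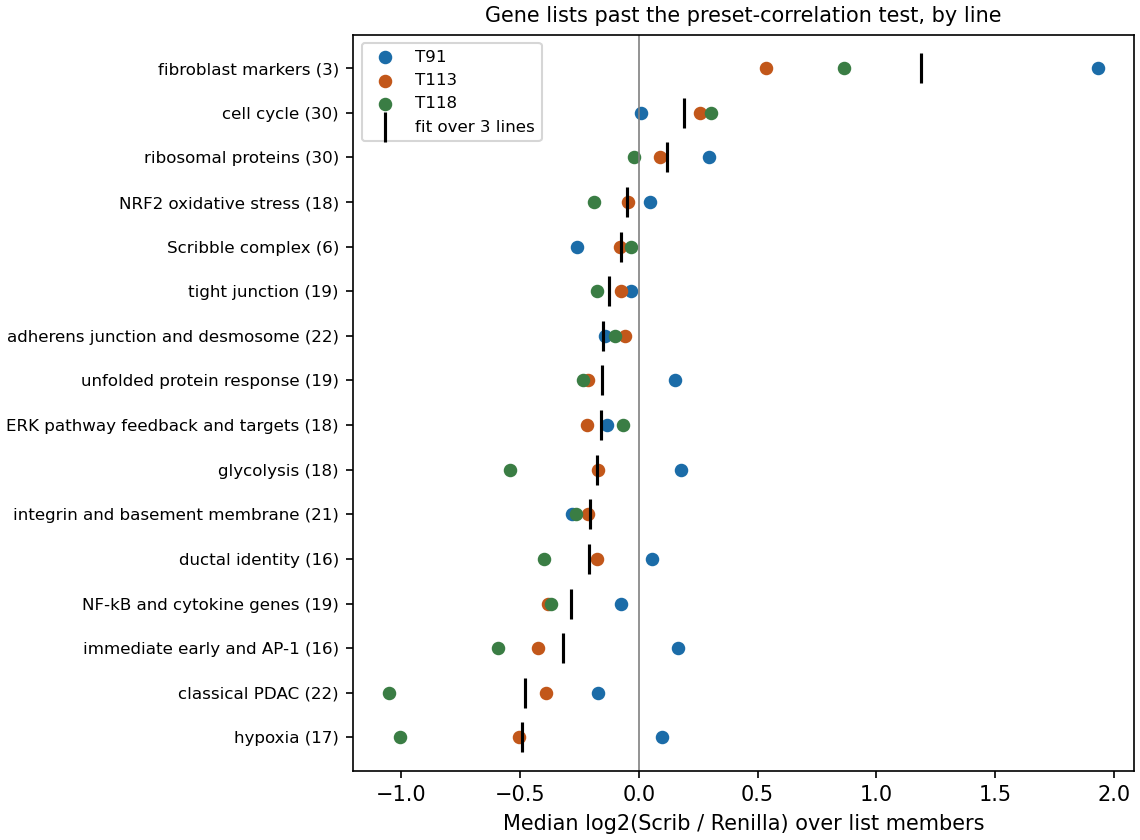
Median log2 ratio of Scrib over Renilla hairpin (x axis) over the measured members of the 16 lists past the camera test with a preset correlation, member numbers in brackets. Coloured points are the medians in T91, T113 and T118 and bars the medians of the fit over the lines, and the hypoxia medians run from -1.01 in T118 to 0.10 in T91.

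The third comparison asked how the tumour lines themselves differ. Each line expressed genes that were close to absent in the others. Col4a1, a basement membrane collagen, was at 147 and 111 CPM in the 2 T91 libraries (Renilla, then Scrib hairpin) and at no more than 3.17 CPM in the 4 others. Igfbp3, which binds insulin-like growth factors, was at 61.4 and 54.8 CPM against at most 1.43, and Ckap4 at 89.6 and 81.8 CPM against at most 1.99. In T113 the gel-forming mucin gene Muc2 was at 60.0 and 45.0 CPM against at most 5.56, and Hepacam2 at 17.2 and 9.05 CPM against at most 1.23. In T118 the brush border protease gene Mep1b was at 35.9 and 12.003 CPM against at most 0.781.

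In all, 1989 of the 14169 genes differed between lines (edgeR's quasi-likelihood F-test of both line terms, adjusted p under 0.05), and 4173 had an unadjusted p under 0.05. Pairwise, 859 genes separated T91 from T113, 449 of them higher in T91. T91 and T118 differed in 1564 genes, 822 of them higher in T91, and T113 and T118 in 1452, 757 of them higher in T113. Genes higher in 1 line than in both others numbered 160 for T91, 111 for T113 and 219 for T118, among those that met the rule for named genes. The other T91 genes picked were Slco3a1, at 24.5 and 19.4 CPM against at most 0.423, and Gprc5c, at 14.5 and 10.9 CPM against at most 0.377 and with 0 counts in both T118 libraries. For T113 they were Fam174b, at 44.5 and 43.7 CPM against at most 0.925, and Xlr3a and Xlr3b, at 55.0 and 39.8 CPM in the control library, 2 members of an X-linked family of near-identical copies whose separate levels are uncertain. For T118 they were the netrin receptor gene Unc5c, at 22.5 and 7.14 CPM, Nlrp6, at 42.7 and 14.9 CPM, and Sgsm1, at 27.6 CPM in both. The lines differed in 15 of 22 classical, 11 of 19 NF-kB, 9 of 20 YAP and TAZ, 9 of 21 integrin and basement membrane, 8 of 13 Wnt and 8 of 16 TGF-beta list members. They differed in 1 of 30 cell cycle, 0 of 30 ribosomal protein and 0 of 27 oxidative phosphorylation genes.

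Sex-linked genes matched the labels. Xist was at 687 and 329 unnormalised CPM in the T91 control and knockdown libraries and at no more than 0.234 in the libraries of the male lines. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 14.1 to 51.5 unnormalised CPM in the male lines and at no more than 0.0832 in T91. Sex and passage go with the line, so neither can be separated from it. Leaving out single libraries moved the count of line differences to 4225 without the T91 control, 3572 without the T91 knockdown, 3055 without the T118 control, 1124 without the T113 control and 1113 without the T113 knockdown library.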

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

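The tests in this part were chosen after the pattern each one addresses was seen, but before its own result was. Each difference between lines given here was not tested, because there was 1 pair of libraries per line, and it drew attention because 1 line lay on the other side of 0 from both others.

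Hypoxia genes had a median log2 ratio of Scrib over Renilla hairpin of 0.0957 in T91 against -0.505 in T113 and -1.01 in T118, so T91 stood above the mean of the others by 0.852. Thinning each pair to equal totals left a gap of 0.855. The ratios were already scaled for library size and the members had a median of 72.9 CPM, so thinning could hardly move them. It therefore does not decide on unequal depth as a cause. Removing the trend on GC content and gene length within each line left 0.782, which argues against such a bias as the whole cause. Also open is any feature of the line itself, such as its tumour, sex or passage, and the state of the cultures at harvest (density or oxygen supply may differ between them), which the sources used here do not describe.

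The classical PDAC list had a median log2 fold change of -0.48 over the lines. It was -0.44 after removing the trend on GC content and length, which argues against such a bias as the whole cause. It was -0.48 after thinning each pair to equal totals. Thinning could hardly move members with a median of 40.1 CPM, so it does not decide on depth. General epithelial genes had a median of -0.17, so a smaller share of epithelial cells would not account for the size of the change. An effect of the single hairpin on other transcripts stays open and untested, as does the state of the cultures. Chance stays open too. The list had an adjusted p of 0.625 by camera with an estimated correlation and of 0.376 by fry's directional test. Camera in that setting called 0 lists in every split of the libraries and the lowered list in 0 of 3 simulated runs. Its result therefore cannot decide on chance, and the splits are too few to do so. Lower expression of this programme when Scrib is depleted is therefore a hypothesis, and it would need a second hairpin.

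7 genes had at least 10 counts in each library of one group and 0 in each library of the other, 3 of them in knockdown libraries alone (Gm13040, Gm3183 and Gm2446) and 4 in control libraries alone (Gm12161, Gm15725, Gm17131 and Gm2436). For 6 of the 7, with Gm17131 as the exception, 90% or more of the transcript occurs base for base in another gene, which is consistent with reads being assigned to one of several near-identical copies. Gm2436 and Gm2446 are such a pair, and their summed level was 4.87 ± 0.763 CPM in control and 4.12 ± 0.553 CPM in knockdown libraries (SD, n = 3 each), a log2 ratio of -0.24 ± 0.42 (SD, n = 3 lines). The sources used here do not say whether both groups were quantified in one run, so a difference in processing between the groups stays open and untested, and comparisons of such genes are uncertain. The real grouping gave 7 such genes and the highest of the other splits gave 5, with 1 of the 10 splits as large, and 10 splits are too few for a share under 0.05.

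The 10 splits of the libraries are also too few for the other counts. For genes changed, the real split gave 1 and 7 of the 10 gave as many, the highest other with 86. Among the splits with 86 genes each parts the T118 pair alone, so the count is that of the T118 pair set against the spread of the others and points to a structure of the samples, and with the line term some splits are mirror images of one another. Among the 3 other splits that part all pairs the highest count was 3. For gene lists the real split gave 16 and 2 of the 10 gave as many, the highest other with 18, which sets the T91 control with the T113 and T118 knockdowns.

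Immediate early and AP-1 genes had a median log2 ratio of 0.164 in T91 against -0.425 in T113 and -0.594 in T118. Glycolysis genes had one of 0.18 in T91 against -0.17 and -0.543. Ductal identity genes had one of 0.0555 in T91 against -0.176 and -0.399. Unfolded protein response genes had one of 0.153 in T91 against -0.216 and -0.237. NRF2 targets had one of 0.046 in T91 against -0.0475 and -0.187. Ribosomal protein genes differed the other way round, with -0.021 in T118 against 0.297 in T91 and 0.0888 in T113. Single genes with a ratio above 0 in T91 and below it in T113 and T118 included Ier3 (0.0448 against -0.904 and -0.728) and Klf6 (0.00132 against -0.622 and -0.469). Egr1 (0.0286 against -0.462 and -0.547) and Dnajb9 (0.0451 against -0.807 and -0.88) were further examples.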

How the results depend on the processing

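Besides the tests of the part before, those chosen after the data were seen were the count of lists with the tested direction in each line, DESeq2 size factors for the lists and the test without clone-named genes. Scrib stayed past the threshold under every alternative run, with a log2 fold change from -2.48 without T113 to -2.28 without T91. The count of changed genes was 1 under each alternative but these: 64 without the low-count filter, 60 with DESeq2, 8 with limma-voom, 8 with DESeq2 and no line block, and 9 to 94 when a line was left out (94 without T91, 9 without T113, 25 without T118). DESeq2 shared 39 of the 64 genes and all of the 8 of limma-voom, of which 7 have 0 counts in one group. Without the line block edgeR's fit also called 1 gene, and leaving out the block ended the calls of 2 lists (adherens junction and NRF2) and no other. Line differences ran from 1113 to 4225 when single libraries were left out, against 1989, and stayed within 1.5 times of it under the other alternatives. The 16 calls of lists went to 0 with an estimated correlation, 0 by fry's directional test and 2 by its mixed test, and 9 of the 16 had the tested direction in each line. The count of lists called was 14 without the line block, 19 without the filter, and 11 to 18 without single lines. With single lines left out, log2 fold changes ran from -0.255 without T118 to 0.031 without T91 for Dlg1 and from -0.0858 to 0.0153 for Llgl1 likewise, and the glycolysis list went from an adjusted p of 4.76e-07 (camera with Benjamini-Hochberg adjustment; lower, without T91) to 0.733 (turned upward, without T118). The cause was not tested for any of these. Over all alternatives, 1029 values of named genes kept their direction and side of the threshold, 40 came past it and 2 reversed. For called lists 81 kept both, 45 lost the call and 1 reversed. The fibroblast list and Col1a2 without T118, and genes below the stricter filter, gave no value. In simulation edgeR found few 1.5-fold changes at this depth and replicate number (0.498%) and DESeq2 more (35.8%), with 30% of the calls of DESeq2 false, so edgeR's test would miss most changes of that size.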

Other observations

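The genes in this part were chosen after their values were seen, and no test was made for them beyond those named. DESeq2 called 60 genes after knockdown, and those given here were among them. In simulation 192 of its 640 calls over 3 runs (30%) were false. That share depends on how many genes were changed there, so the false share among the 60 is not known. Lower by DESeq2 were Galnt7, a transferase that starts or extends mucin-type glycans (log2 fold change -0.61, DESeq2 adjusted p of 0.000319, given in this order from here on), B4galnt2, a glycosyltransferase of mucosal epithelium (-0.95, 0.000104), and Gfpt1, which opens the hexosamine pathway (-0.48, 0.00881). Ern2, a stress sensor of mucus-secreting cells, was at -1.24 (0.00115), Creb3l1, a membrane-bound transcription factor of secretory cells, at -1.44 (0.0112) and Vsig1, a junctional protein of gastric epithelium, at -0.92 (0.00115). None of these passed edgeR's test, where their adjusted p ran from 0.397 to 0.693 with Benjamini-Hochberg adjustment.

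Several genes that set T118 apart from the other lines were lower in the T118 knockdown than in its control, with 1 library each. Mep1b was at 35.9 CPM in the control and 12.003 in the knockdown, Unc5c at 22.5 and 7.14, and Nlrp6 at 42.7 and 14.9, whereas Sgsm1 was at 27.6 in both. In T113, 2 of the islet markers, Chgb and Neurog3, were at 8.61 and 6.31 and at 2.65 and 1.41 unnormalised CPM (control, then knockdown), and at no more than 0.368 and 0.167 in the other lines. Ins1, Ins2 and Iapp had 0 counts in every library. In T91, Xist was at 687 unnormalised CPM in the control and 329 in the knockdown library. There, 306 other X-linked genes with an average log2 CPM of at least 2 had a median log2 ratio of -0.05, against 0.01 for 10114 such autosomal genes.

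The log2 ratios of the lines were compared across genes, with 1 pair of libraries per line. Across the 9513 genes with an average log2 CPM of at least 3, the log2 ratios of T113 and T118 correlated at a Pearson r of 0.546. Those of T91 and T113 correlated at 0.083 and those of T91 and T118 at -0.177. These are correlations across genes, which are not independent replicates. An absolute log2 ratio of at least 1 was reached by 156 of these genes in T118 (151 lower), 55 in T91 (49 lower) and 29 in T113 (23 lower).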
